A study of Mus musculus with 31 samples.

How the data were processed

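Transcript levels were measured in D10.G4.1 cells, a clone of mouse type 2 helper T (Th2) cells, after treatment with the peptide neuromedin U (NmU) or with phosphate-buffered saline (PBS). Per the labels, cells were sampled at 0.8, 3, 6 and 12 h, and 31 total RNA samples were hybridised to 1 array each. Each of the 8 groups of treatment and time held 4 arrays, except NmU at 3 h, which held 3. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates of a group were separate cultures, so that p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

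The deposited values were 1-colour probe set intensities on a linear scale, never below 0, and 162 of them were exactly 0. The scanner, the summary of probes into probe sets and the scaling used by the authors are not given in the sources used here. From the values themselves, the mean of each array after 2% of probe sets were taken off each end lay between 149.96 and 149.97, and the median signal between 34.4 and 43.3. The arrays had therefore been scaled to a common mean before deposit. A rule set before the data were examined called for no further normalisation where these means lay within 10% of that of the median array, and the intensities were used as deposited. The global scaling assumes that total signal was equal in all samples, so that a change is relative to the other transcripts on the array.

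The table held 12488 probe sets, of which 66 were array controls and were left out of the tests. Of the other 12422, the probe table paired 10833 with a single gene symbol, 396 with several and 1193 with none. A probe set paired with several genes names no gene here. Symbols were checked against a RefSeq gene table of assembly GRCm38.p6 through Entrez gene numbers, which matched 10817 of the 10833 probe sets and changed 0 symbols. No genome build is named for the array, and no coordinates are given. Where a gene had several probe sets, the probe set with the highest mean over the 31 arrays stood for it.

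Intensities under 5.8, the 20th percentile of all values, were raised to that floor, and log2 was taken. On the arrays, between 15.4% and 24.1% of probe sets lay at or below the floor. A probe set was kept if its mean log2 value was above the 40th percentile of all values, a signal of 20.2, in at least 1 group. This kept 7930 probe sets for 5905 genes. Changes of dim transcripts are understated by the floor, and where every array of a group lay at the floor the fold is a lower bound.

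All 31 arrays entered a single linear model with a mean for each of the 8 groups, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 23 residual and 2.72 prior degrees of freedom). The contrasts were NmU minus PBS at each time. Moderated F tests asked whether a probe set changed at any time, whether its effect differed between times, and whether it changed with time in PBS. P-values were two-sided, were adjusted by the Benjamini-Hochberg method over the 7930 probe sets of each contrast, and a probe set was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from limma, and signals are given as mean ± SD of the deposited values.

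Gene lists were fixed before the data were examined. There were 26, covering cytokines, chemokines, signalling targets, T helper identity, the cell cycle, metabolism, stress responses, and markers of other cell types. The 23 lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 92 tests of list and time. The same test with an estimated correlation was run beside it, and so was the rotation test fry, which tests a list alone and is not reported here. The 12 genes with the largest increase and the 12 with the largest decrease among those called at each time, all measured Th2 cytokines, up to 4 members of every other list with the lowest p, and the receptor Nmur1 could be named in the text by a rule set before the data were examined. For time in PBS the rule took the 10 genes with the largest rise and fall.

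The procedure was tested on simulated data with 200 changed probe sets among 7930. Values were normally distributed around the real mean of each probe set over the PBS arrays, with its residual spread pooled over all groups. The simulated values were not floored and no array stood apart. Recovery of dim probe sets at the floor, or with outlying arrays, is therefore not shown. At 0.8 h the procedure recovered 40% of probe sets changed by 0.50 on the log2 scale. It recovered 78% at 1.00, 98% at 2.00 and 100% at 3.00, with 10 false calls among 168. In the 6 h comparison it recovered 28%, 92%, 96% and 100% at these sizes. For the 3 h comparison it recovered 34%, 72%, 92% and 100%, and for the 12 h comparison 42%, 76%, 98% and 100%. In the simulated 6 h comparison of 7930 probe sets, camera called 20 of 20 lists shifted by 0.50 and 0 of 20 lists left alone. The simulated probe sets were drawn independently and the lists at random. This therefore does not show how often camera calls unshifted lists of correlated genes. The estimated correlation of the real list of interferon-induced genes was 0.533.

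Alternatives tried were quantile normalisation, scaling to a common median, floors at the 10th and 40th percentile, no filter and a filter at the 60th percentile, trended and robust variances, array weights, only the 2 groups compared, an adjusted p under 0.01, an added limit of 1.5-fold, the mean over all probe sets of a gene, camera with an estimated correlation, the replicate number as a block within or across times, and leaving out each array in turn. Leaving out NmU 6 h replicate 4 together with PBS 3 h replicate 4 was chosen after seeing the data. Array controls for RNA quality were compared between treatments with two-sided exact permutation tests. Figures were drawn with matplotlib in Python.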

Results

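The study asked how neuromedin U, a neuropeptide that acts through the G protein-coupled receptors Nmur1 and Nmur2, changes transcript levels in a mouse T cell clone of the Th2 type. Arrays of PBS-treated and NmU-treated D10.G4.1 cells were compared at 0.8, 3, 6 and 12 h, with 4 arrays per group except NmU at 3 h, which had 3. Over 7930 probe sets, array pairs of a group correlated at between 0.951 and 0.982 (median 0.971, across probe sets, which are not independent replicates), and 0 pairs of arrays held identical values. The median signal per array lay between 34.4 and 43.3. Transcripts of Nmur1 were measured at a signal of 201 ± 31.4 (SD, n = 4) in PBS at 0.8 h.

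NmU raised 62 probe sets (54 named genes) and lowered 5 (4 named genes) at 0.8 h. At 3 h it raised 352 and lowered 454, at 6 h it raised 226 and lowered 161, and at 12 h it raised 68 and lowered 32. At least 2-fold increases numbered 33, 89, 53 and 17 at these times, and at least 2-fold decreases 2, 64, 10 and 2. With arrays scaled to a common median the split was 448 higher and 337 lower at 3 h, and 175 higher and 204 lower at 6 h, so that which direction held more calls at these 2 times turned with the scaling. At 3 h it also turned with only the 2 groups compared (110 higher, 61 lower) and with at least 1.5-fold required (233 higher, 227 lower). Quantile normalisation turned it as well (415 higher, 411 lower). The F test over all times called 922 probe sets for 789 named genes. Without NmU 6 h replicate 3 the count at 6 h was 238, without PBS 6 h replicate 1 it was 248 and without NmU 6 h replicate 1 it was 254. The count at 12 h was 66 without NmU 12 h replicate 3.

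**Figure D1:**
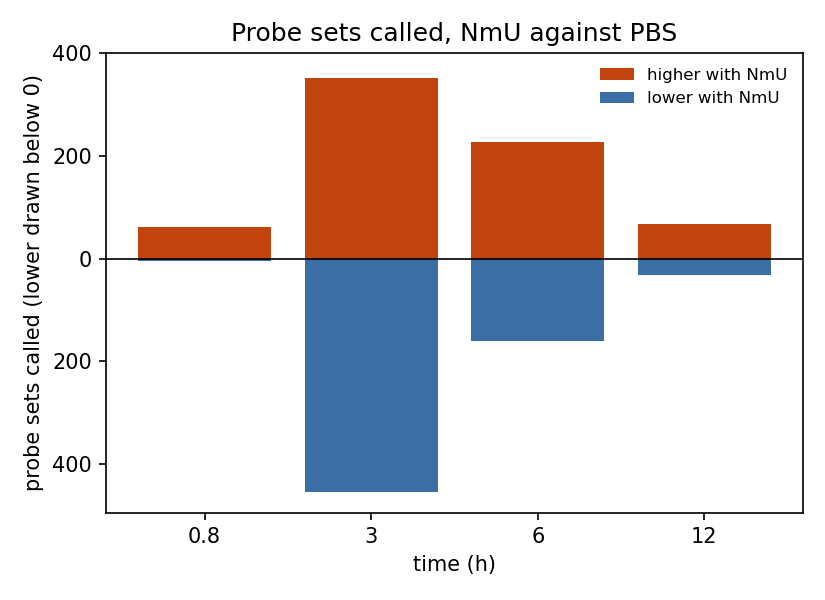
Number of probe sets called with limma at an adjusted p under 0.05 at each time (h), with increases under NmU above 0 and decreases drawn below it. The highest bar of increases, 352, and the longest bar of decreases, 454, are both at 3 h.

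Within 0.8 h, NmU raised transcripts of immediate early genes, which are transcribed within minutes of a stimulus. The zinc finger factor Egr1 rose from a signal of 151 ± 34.5 (SD, n = 4) in PBS to 3499.9 ± 164.5 (SD, n = 4), a log2 fold change of 4.57 ± 0.45 (SE, limma adjusted p = 1.01e-07). Egr2 rose from 129 ± 25.6 to 2953.7 ± 31.1 (SD, n = 4 each; log2 4.54 ± 0.35), and Fos from 30.4 ± 5.68 to 533 ± 46.6 (SD, n = 4 each; log2 4.15 ± 0.45). Of 23 measured immediate early genes, 13 rose, 1 fell and 9 were not called, or 16 and 2 adjusted over the list alone. The list shifted upward with camera (adjusted p = 8.95e-41, and adjusted p = 1.48e-05 with an estimated correlation). Ier2 (log2 2.29 ± 0.19), the nuclear receptor Nr4a1 (2.43 ± 0.30), the RNA-destabilising protein Zfp36 (1.75 ± 0.16), Junb (1.14 ± 0.11) and the phosphatase Dusp1 (0.82 ± 0.14) were among those that rose.

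The hallmark cytokines of Th2 cells were already higher at 0.8 h. Il4 rose from 529 ± 44.3 to 1870.1 ± 67.8 (SD, n = 4 each; log2 1.82 ± 0.11 SE, limma adjusted p = 1.02e-11), Il6 by a log2 fold change of 1.40 ± 0.12, Il10 by 1.36 ± 0.12 and Il13 by 1.08 ± 0.14. Of 7 measured Th2 cytokines, 4 rose and 3 were not called (5 rose adjusted over the list alone; camera adjusted p = 2.72e-20, and adjusted p = 1.77e-05 with an estimated correlation). Il5 differed by 0.10 ± 0.24 (adjusted p = 0.990), Il9 by -0.47 ± 0.28 (adjusted p = 0.858) and Il3 by 1.15 ± 0.41 (adjusted p = 0.350). Il3 passed the test without PBS 3 h replicate 4 (adjusted p = 0.0250), and with all arrays kept and the replicate number as a block within times (adjusted p = 0.00310). A further Il4 probe set was called at all 4 times and moved the same way, by 2.82 at 0.8 h and 4.11 at 3 h.

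Chemokines that attract monocytes and other leukocytes rose with them. Ccl7 rose from 70.3 ± 22.2 to 612 ± 72.9 (SD, n = 4 each; log2 3.19 ± 0.35), and Ccl4 by a log2 fold change of 2.01 ± 0.38. Ccl2 was at the floor on all 4 PBS arrays and was at least 7.34-fold higher with NmU. Of 10 measured chemokines, 3 rose and 7 were not called (5 rose adjusted over the list alone; camera adjusted p = 5.74e-09, and adjusted p = 2.16e-04 with an estimated correlation). The inflammatory cytokine Tnf rose by 2.29 ± 0.22, the inhibitory receptor Ctla4 by 2.54 ± 0.32 and the ADP-ribosyltransferase Tiparp by 2.03 ± 0.29 (limma adjusted p = 8.17e-08, 6.90e-06 and 4.96e-05).

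The list of targets of calcineurin and NFAT, the calcium-dependent arm of T cell signalling, shifted upward at 0.8 h. This list also holds genes for subunits of calcineurin and for NFAT factors themselves, which are counted among the targets here and below. Of 13 measured members 4 rose, 9 were not called and 6 rose adjusted over the list alone (camera adjusted p = 5.05e-16, and adjusted p = 1.64e-05 with an estimated correlation). The members that rose were Egr2, Il4, Nr4a1 and Tnf, and all 4 also stand on other lists. Among feedback regulators of signalling 3 of 11 rose, with Dusp1 and the cytokine-signalling inhibitor Cish (0.71 ± 0.12) among them (5 adjusted over the list alone; adjusted p = 1.10e-05, and adjusted p = 0.00278 with an estimated correlation). Th2 identity genes rose in 4 of 10 cases, including the chemokine receptor Ccr8 (1.10 ± 0.21), Junb and Crem (0.71 ± 0.11) (4 adjusted over the list alone; adjusted p = 5.74e-09, and adjusted p = 2.16e-04 with an estimated correlation). NF-kB targets held 2 that rose and 1 that fell among 12, with the same counts adjusted over the list alone, Irf1 rising by 0.70 ± 0.11 (adjusted p = 0.0146, and adjusted p = 0.0899 with an estimated correlation). This shift was not called without PBS 0.8 h replicate 1, where 1 member rose, or without NmU 0.8 h replicate 1 (adjusted p = 0.159 and 0.0513). Of 17 T cell activation markers only Ctla4 rose, also adjusted over the list alone (adjusted p = 0.00241, and adjusted p = 0.120 with an estimated correlation).

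At 0.8 h 4 named genes were lower. The transcription factor Klf10 fell by 1.03 on the log2 scale (SE 0.15, limma adjusted p = 7.00e-05), the stress protein Gadd45b fell by 0.69 (SE 0.11), the mTOR inhibitor Ddit4 fell by 0.67 (SE 0.13) and the repressor Gfi1 fell by 0.46 (SE 0.11, adjusted p = 0.0401). The Gfi1 call was lost without any of PBS 0.8 h replicates 1, 2 and 4 and NmU 0.8 h replicates 1, 3 and 4, at adjusted p between 0.0606 and 0.217, and also, with the fold left as it was, without several arrays of other times. The apoptosis regulator Cflar rose by 0.97 ± 0.18.

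**Figure D2:**
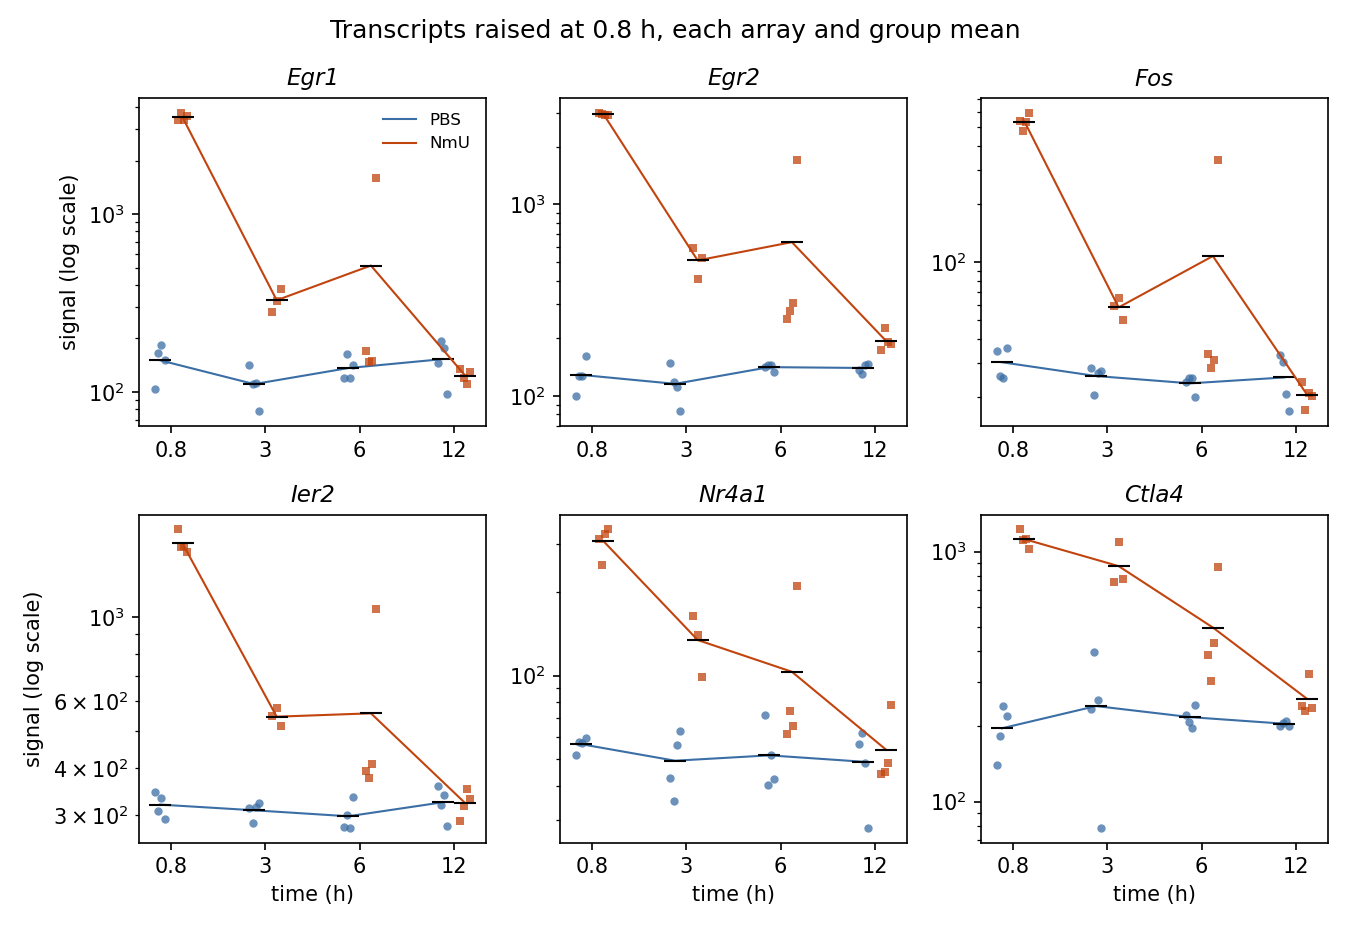
Signal (log scale) of Egr1, Egr2, Fos, Ier2, Nr4a1 and Ctla4 on each array at 0.8, 3, 6 and 12 h (times evenly spaced on the axis), with circles for PBS, squares for NmU and black bars with lines for group means. The 4 NmU arrays at 0.8 h lie above all PBS arrays of that time, and at 6 h NmU replicate 4 lies far above the other 3 NmU arrays, with an Egr1 signal of 1586.7.

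At 3 h, the Th2 cytokines and chemokines stood at their highest fold changes for Il4, Il13, Ccl1 and Ccl7. Il4 rose from 504.5 ± 76.5 (SD, n = 4) to 3284.4 ± 610 (SD, n = 3), a log2 fold change of 2.70 ± 0.11 (SE, limma adjusted p = 5.01e-15). Il13 rose by 1.75 ± 0.15, Il10 by 1.34 ± 0.13, Il6 by 1.35 ± 0.13 and Il3 by 2.10 ± 0.44. The eosinophil growth factor Il5 rose by 1.74 ± 0.26 (adjusted p = 3.52e-05), from 60.3 ± 6.78 (SD, n = 4) to 226 ± 142 (SD, n = 3). Of the 7 Th2 cytokines, 6 rose, also adjusted over the list alone, and Il9 was not called at 0.31 ± 0.30 (camera adjusted p = 4.42e-15, and adjusted p = 1.07e-04 with an estimated correlation).

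Ccl7 reached 1120.2 ± 239 (SD, n = 3) against 58.8 ± 30.5 (SD, n = 4), a log2 fold change of 4.51 ± 0.38, and Ccl1, a ligand of Ccr8, reached 1213.6 ± 308 (SD, n = 3) against 94.7 ± 34.6 (SD, n = 4; log2 3.72 ± 0.30). Ccl4 rose by 3.30 ± 0.41 and Ccl3 by 2.11 ± 0.32. Ccl2 was at least 8.01-fold higher, with all 4 PBS arrays at the floor. At 3 h, 6 of 10 chemokines rose, also adjusted over the list alone (camera adjusted p = 3.95e-08, and adjusted p = 3.62e-04 with an estimated correlation). The small GTPase Gem rose by 2.49 ± 0.35, the CD30 ligand Tnfsf8 by 2.23 ± 0.22 and Slfn2, a gene linked to T cell quiescence, by 2.08 ± 0.19.

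Signalling lists were also higher at 3 h. Of 23 immediate early genes 11 rose, with Egr2 at 2.15 ± 0.37 (15 higher and 1 lower adjusted over the list alone; adjusted p = 8.94e-08, and adjusted p = 0.0316 with an estimated correlation, or 0.0566 with an estimated correlation once PBS 3 h replicate 4 was left out). Of 13 members of the calcineurin and NFAT list 6 rose and 1 fell, with Nfatc1 at 1.08 ± 0.18 (7 and 2 adjusted over the list alone, camera adjusted p = 3.73e-05, and adjusted p = 0.00938 with an estimated correlation). The member that fell was a subunit of calcineurin itself. NF-kB targets rose in 4 of 12 cases, Nfkbia by 0.93 ± 0.14, Relb by 1.07 ± 0.15 and Gadd45b by 0.66 ± 0.12 (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00232, and adjusted p = 0.0316 with an estimated correlation). Feedback regulators held 3 higher and 1 lower of 11, with the ERK phosphatase Dusp6 at 1.02 ± 0.13 (6 and 1 adjusted over the list alone; adjusted p = 0.0233, and adjusted p = 0.120 with an estimated correlation). Their shift was not called without NmU 3 h replicate 1 (adjusted p = 0.0944), and 5 rose without PBS 3 h replicate 4. Activation markers rose in 4 of 17 cases, with Ctla4 at 2.05 ± 0.34 and the adhesion receptor Cd44 at 1.40 ± 0.26 (6 adjusted over the list alone; adjusted p = 0.00185, and adjusted p = 0.120 with an estimated correlation). Among Th2 identity genes Crem rose by 1.34 ± 0.12, while the receptor chain Il4ra fell by 0.96 (SE 0.17) and the transcription factor Irf4 fell by 0.64 (SE 0.12). The mean over all probe sets of Il4ra was not called (-0.51, adjusted p = 0.129), nor was Il4ra with only the 2 groups compared (adjusted p = 0.0747). Of the 10, 4 rose and 2 fell, the same adjusted over the list alone, with no shift of the list (adjusted p = 0.146), and 2 rose without NmU 3 h replicate 1 or 3. Of ribosome biogenesis genes 3 of 15 rose, also adjusted over the list alone (adjusted p = 5.46e-04, and adjusted p = 0.250 with an estimated correlation). Without PBS 3 h replicate 4, 7 of them rose, and without PBS 3 h replicate 2 or NmU 3 h replicate 1, 1 rose. The NF-kB shift had an adjusted p of 0.0644 with an estimated correlation without that array.

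Several genes of the cell cycle were lower at 3 h. At 0.8 h 0 of 21 genes of mitosis and 0 of 20 genes of DNA replication had been called (camera adjusted p = 0.530 and 0.801). Of 21 measured genes of mitosis and G2/M, 8 fell and 0 rose (10 lower adjusted over the list alone; camera adjusted p = 2.71e-06, and adjusted p = 0.148 with an estimated correlation). The mitotic kinases Aurkb, Aurka and Plk1 fell by 0.82 (SE 0.14), fell by 0.75 (SE 0.11) and fell by 0.67 (SE 0.11) on the log2 scale. Of 20 genes of DNA replication and G1/S, 5 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00132, and adjusted p = 0.282 with an estimated correlation). Thymidine kinase Tk1 fell by 0.55 (SE 0.11) and the G1 cyclin Ccnd3 fell by 0.67 (SE 0.12), while Ccnd2, also a G1 cyclin, rose by 1.02 ± 0.16. Without PBS 3 h replicate 4, which stood apart from its group, the DNA replication shift was not called (adjusted p = 0.0697) and 3 of its members were lower, while 7 genes of mitosis were lower (adjusted p = 0.00114). Without NmU 3 h replicate 2 or 3, 3 genes of DNA replication were lower. With only the 2 groups compared, Aurkb, Aurka, Plk1 and Tk1 were not called (adjusted p = 0.104, 0.0937, 0.0747 and 0.0958), nor was Ccnd3.

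The proto-oncogene Myb fell from 820 ± 120 (SD, n = 4) to 240 ± 16.0 (SD, n = 3) at 3 h (log2 fell by 1.76, SE 0.13, limma adjusted p = 1.09e-09). The transcription factor Mef2c fell by 2.23 (SE 0.35), with 1 of 3 NmU arrays at the floor, and was not called with the floor at the 40th percentile (-0.80, adjusted p = 0.128). The adhesion receptor Adgrg1 fell by 1.64 (SE 0.18). The caspase activator Apaf1 fell by 1.03 (SE 0.11), and the T cell receptor kinase Zap70 rose by 0.76 ± 0.11.

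**Figure D3:**
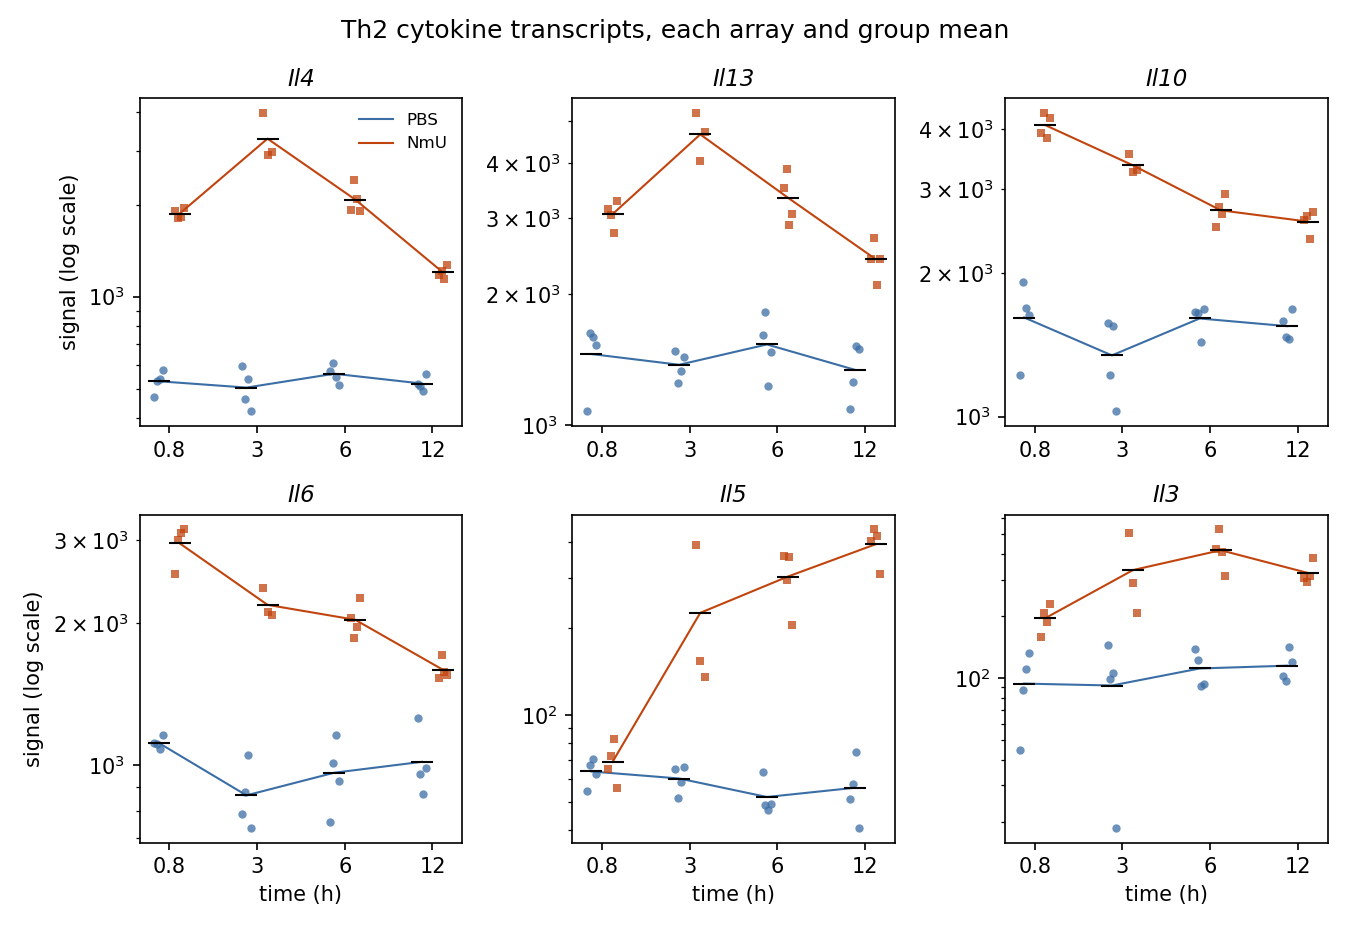
Signal (log scale) of Il4, Il13, Il10, Il6, Il5 and Il3 on each array at 0.8, 3, 6 and 12 h (times evenly spaced on the axis), with circles for PBS, squares for NmU and black bars with lines for group means. Group means of Il5 under NmU run from 68.8 at 0.8 h to 391 at 12 h, and those of Il4 from 1870.1 at 0.8 h through 3284.4 at 3 h to 1199.8 at 12 h.

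At 6 h, Il5 and the enzymes of cholesterol synthesis came to the fore. Il5 rose from 52.0 ± 7.72 to 302 ± 71.7 (SD, n = 4 each; log2 2.52 ± 0.24 SE, limma adjusted p = 1.09e-07) and Gem from 18.9 ± 7.22 to 200.1 ± 47.2 (SD, n = 4 each; log2 3.44 ± 0.33). Of 14 measured cholesterol synthesis genes 9 rose (11 adjusted over the list alone), and the list shifted upward (camera adjusted p = 2.38e-13, and adjusted p = 1.07e-04 with an estimated correlation). Squalene epoxidase Sqle rose by 1.21 ± 0.15, the methyl sterol oxidase Msmo1 by 1.28 ± 0.17, the isomerase Idi1 by 1.07 ± 0.17 and the synthase Hmgcs1 by 1.03 ± 0.16. At 3 h, 3 of the 14 had risen, or 6 higher and 1 lower adjusted over the list alone, with no shift of the list (adjusted p = 0.0854).

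Of the 7 Th2 cytokines, 6 rose at 6 h, also adjusted over the list alone (camera adjusted p = 6.35e-16, and adjusted p = 9.72e-05 with an estimated correlation). Il4 rose by 1.89 ± 0.11, Il3 by 1.91 ± 0.41, Il13 by 1.12 ± 0.14, Il6 by 1.09 ± 0.12 and Il10 by 0.75 ± 0.12, and Il9 was not called at 0.26 ± 0.28. Of 10 chemokines 6 rose, also adjusted over the list alone, led by Ccl3 (2.16 ± 0.30), Ccl1 (2.10 ± 0.27), Ccl7 (2.02 ± 0.35) and Cxcl2 (1.81 ± 0.25) (adjusted p = 2.46e-08, and adjusted p = 3.26e-04 with an estimated correlation). Calcineurin and NFAT targets rose in 4 of 13 cases, with Tnf at 1.27 ± 0.22 (7 higher and 1 lower adjusted over the list alone; adjusted p = 1.23e-04, and adjusted p = 0.0150 with an estimated correlation). NF-kB targets rose in 2 of 12 cases, or in 0 to 3 with single arrays left out (5 higher and 2 lower adjusted over the list alone) with no shift of the list (adjusted p = 0.134). Feedback regulators rose in 1 of 11 cases, Dusp6 at 0.70 ± 0.12 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.102). Of these, 3 were higher without PBS 3 h replicate 4. Without NmU 6 h replicate 4, 1 was lower. Activation markers held 4 higher and 1 lower of 17, or 1 to 5 higher and 0 to 1 lower with single arrays left out, with Cd44 at 1.14 ± 0.24 (6 and 1 adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.224 with an estimated correlation). Ribosome biogenesis held 1 higher of 15, also adjusted over the list alone (adjusted p = 0.0219, and adjusted p = 0.441 with an estimated correlation), a shift not called without NmU 6 h replicate 2 or 3 (adjusted p = 0.0974 and 0.0520).

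Of 23 immediate early genes 5 rose at 6 h, with the AP-1 member Fosl1 at 1.41 ± 0.21 (9 adjusted over the list alone; adjusted p = 9.79e-07, and adjusted p = 0.0482 with an estimated correlation). The call with an estimated correlation was lost in 22 of the 31 fits with 1 array left out, at an adjusted p of up to 0.0858, PBS 3 h replicate 4 among them (0.0528). Without PBS 6 h replicate 1, 3 of these genes rose. NmU 6 h replicate 4 held an Egr2 signal of 1705.4, against 252 to 304 on the other 3 arrays of its group. The log2 fold change of Egr2 was 1.63 ± 0.35 with this array and 0.97 without it (adjusted p = 2.40e-04). Without it 4 immediate early genes, 5 chemokines, 2 activation markers and 10 cholesterol synthesis genes were higher at 6 h. Other genes named for 6 h also lay towards their 0.8 h level on NmU 6 h replicate 4. Cxcr4 was at 75.2 against a mean of 29.3 on the other 3 arrays, and Ccl7 at 440 against 281. Il5 was at 204.6 against 335, and Idi1 at 285 against 429. Fold changes given for 6 h include this array unless said otherwise.

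Several cell cycle genes were lower at 6 h too. Of 21 genes of mitosis and G2/M 7 fell, among them cyclin Ccnb2, which fell by 0.44 (SE 0.09) (12 adjusted over the list alone; camera adjusted p = 5.77e-07, and adjusted p = 0.120 with an estimated correlation). Of 20 genes of DNA replication 2 fell and 1 rose, and polymerase subunit Pola1 fell by 0.59 (SE 0.12), a call lost with only the 2 groups compared (adjusted p = 0.0686), as was that of Ccnb2 (adjusted p = 0.0949) (8 and 1 adjusted over the list alone; adjusted p = 3.06e-04, and adjusted p = 0.239 with an estimated correlation). With single arrays left out, the number of lower genes ran from 2 to 10 for mitosis and from 1 to 4 for DNA replication. For mitosis it was 2 without PBS 6 h replicate 3, 3 without NmU 6 h replicate 1 or 3, and 4 without PBS 6 h replicate 4 or NmU 6 h replicate 2. For DNA replication it was 4 without PBS 3 h replicate 4 or NmU 6 h replicate 2, and 1 without PBS 6 h replicate 1, 2 or 4 or NmU 6 h replicate 1, 3 or 4. Ddit4 fell from 611 ± 24.1 to 284 ± 20.4 (SD, n = 4 each), which on the log2 scale fell by 1.11 (SE 0.13, limma adjusted p = 1.83e-06). The chemokine receptor Cxcr4 fell by 1.21 (SE 0.24) and Dennd5a, a guanine nucleotide exchange factor, fell by 0.77 (SE 0.10). Th2 identity genes were not called at 6 h (0 of 10, or 3 lower adjusted over the list alone; list adjusted p = 0.275).

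At 12 h, Il5 led the response, rising from 56.0 ± 14.2 to 391 ± 58.0 (SD, n = 4 each; log2 2.83 ± 0.24 SE, limma adjusted p = 2.65e-08). Il4 rose by 1.21 ± 0.11, Il13 by 0.85 ± 0.14, Il10 by 0.73 ± 0.12 and Il6 by 0.66 ± 0.12. Il3 (adjusted p = 0.0739) and Il9 (1.03 ± 0.28, adjusted p = 0.0713) did not pass the test over all probe sets. Il3 passed without PBS 3 h replicate 4 (adjusted p = 0.00173), and Il9 without PBS 12 h replicate 2 (adjusted p = 0.00459). With all arrays kept, Il3 also passed with quantile normalisation, a filter at the 60th percentile, trended and robust variances, array weights or only the 2 groups compared (adjusted p = 0.0491, 0.0389, 0.0426, 0.00757 and 0.00329). Il9 passed with quantile normalisation (adjusted p = 0.0168). Thus 5 of 7 Th2 cytokines rose, or 7 adjusted over the list alone (camera adjusted p = 4.57e-21, and adjusted p = 1.64e-05 with an estimated correlation).

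Chemokines were higher at 12 h in 3 of 10 cases, and in 1 without PBS 12 h replicate 1 or NmU 12 h replicate 2 (6 adjusted over the list alone; camera adjusted p = 7.88e-08, and adjusted p = 4.39e-04 with an estimated correlation). Ccl3 rose by 2.44 ± 0.30 and Ccl4 by 1.67 ± 0.38 (adjusted p = 0.0209). The Ccl4 call was lost without PBS 12 h replicate 1 or 3 or NmU 12 h replicate 1, 2 or 3, at adjusted p between 0.0657 and 0.115. Gem rose by 1.62 ± 0.33, and the probe set paired with Pth, the parathyroid hormone gene, rose from 484 ± 28.1 to 1449.4 ± 78.6 (SD, n = 4 each; log2 1.58 ± 0.12). The signalling adaptor Traf1 (1.42 ± 0.24), Lilr4b (1.24 ± 0.14), Slfn2 (1.08 ± 0.18) and the activation marker Lag3 (0.55 ± 0.11) also rose.

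NF-kB targets rose in 3 of 12 cases at 12 h, also adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.107 with an estimated correlation). The shift was not called without PBS 12 h replicate 1 (adjusted p = 0.0907), and 1 target rose without this array, PBS 12 h replicate 3 or NmU 12 h replicate 4. Immediate early genes rose in 2 of 23, Myc by 0.84 ± 0.16 (3 adjusted over the list alone; adjusted p = 0.0427, and adjusted p = 0.433 with an estimated correlation), a shift not called without PBS 12 h replicate 4 or NmU 12 h replicate 2 or 4 (adjusted p = 0.185, 0.0767 and 0.0557). Of 13 calcineurin and NFAT targets Il4 rose (2 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.113 with an estimated correlation). The number that rose was 2 without PBS 3 h replicate 4. Cholesterol synthesis shifted upward with 0 of 14 members called, or 2 adjusted over the list alone (adjusted p = 3.06e-04, and adjusted p = 0.0349 with an estimated correlation). Members called were 2 without PBS 3 h replicate 4. The number was 1 without PBS 3 h replicate 1 or 2, NmU 3 h replicate 1 or NmU 6 h replicate 2 or 4. With an estimated correlation the shift was not called without PBS 12 h replicate 2 or 3 or NmU 12 h replicate 1 or 3 (adjusted p = 0.0743, 0.0649, 0.0971 and 0.0617). DNA replication (0 of 20 called, also adjusted over the list alone; adjusted p = 6.51e-04, and adjusted p = 0.253 with an estimated correlation) and mitosis (0 of 21 called, 2 lower adjusted over the list alone; adjusted p = 1.80e-06, and adjusted p = 0.142 with an estimated correlation) shifted downward. Ribosome biogenesis shifted upward with 0 of 15 called, or 1 adjusted over the list alone (adjusted p = 0.0267, and adjusted p = 0.448 with an estimated correlation), and was not called without PBS 12 h replicate 3 or NmU 12 h replicate 3 or 4 (adjusted p = 0.0651, 0.0855 and 0.0545). Lists of feedback regulators (0 of 11), activation markers (1 of 17) and Th2 identity (0 of 10) did not shift at 12 h (adjusted p = 0.239, 0.382 and 0.924), with 0, 1 and 1 members higher adjusted over the list alone.

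Among genes lower at 12 h, the fatty acid-binding protein Fabp5 fell by 0.87 (SE 0.13), the calcium-binding proteins S100a1 and S100a13 fell by 0.78 (SE 0.13) and fell by 0.76 (SE 0.08), the decoy receptor Il1r2 fell by 0.77 (SE 0.11) and Myb fell by 0.76 (SE 0.12).

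**Figure D4:**
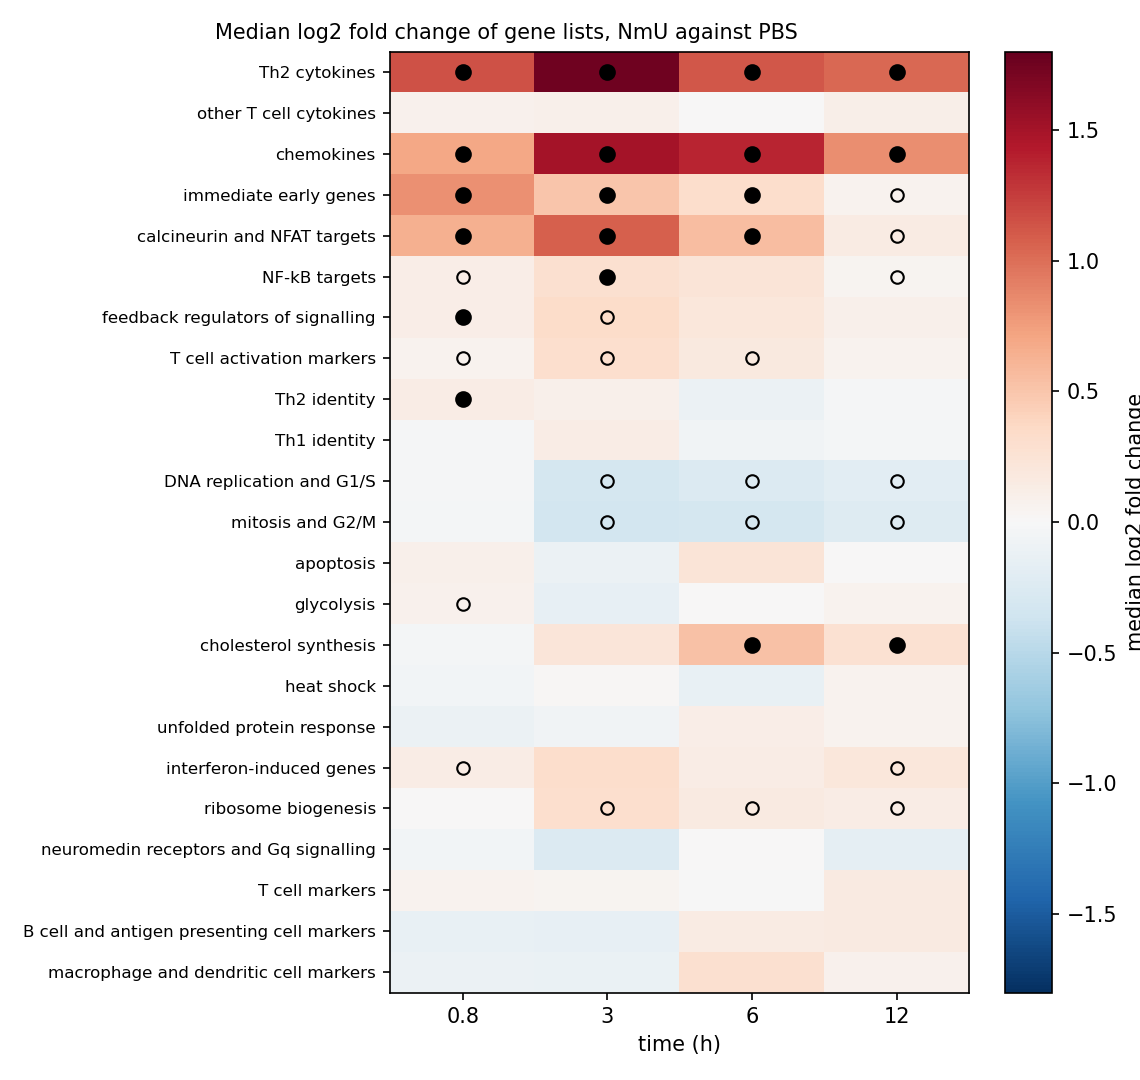
Median log2 fold change (NmU against PBS) of the 23 gene lists tested at each time (h), in colour. Filled circles mark shifts called by camera with both correlations, and open circles those called only with the preset correlation; 19 of the 39 shifts called with the preset correlation were also called with the estimated correlation, all 19 upward.

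Of the 92 tests of list and time, 39 were called with the preset correlation (33 upward, 6 downward) and 19 with the estimated correlation. With each array left out in turn, 30 of the 39 and 15 of the 19 were called in every fit. Scaling to a common median or quantile normalisation turned the median of 0 of these 39. In the 39, the signs of median, mean and test matched, while they differed in 13 of the other tests.

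Few members of the remaining programmes were called. Of 8 other T cell cytokines, Tnf rose at 0.8 h, 2 rose and 1 fell at 3 h, 2 rose at 6 h, or 1 without any of PBS 6 h replicates 1 to 4 or NmU 6 h replicates 1 and 2, and 0 were called at 12 h. Adjusted over the list alone these were 1 higher, 3 higher and 1 lower, 2 higher, and 0. The list did not shift (camera adjusted p = 0.112, 0.465, 0.297 and 0.789 in order of time). The probe sets for Il2, a T cell growth factor, and Ifng, the cytokine of Th1 cells, were dim on all 31 arrays. Their highest signals were 1.70 and 6.00. An array control for Il2, left out of the tests, had its highest signal, 16.7, on PBS 3 h replicate 3. On the other arrays this control reached at most 6.3, on PBS 0.8 h replicate 3. Interferon-induced genes held 1 higher of 16 at 0.8 h, Irf1, also adjusted over the list alone. The list shifted upward at 0.8 h (adjusted p = 0.00158, and adjusted p = 0.433 with an estimated correlation) and at 12 h with 0 called (adjusted p = 0.0205, and adjusted p = 0.576 with an estimated correlation). These shifts were not called without PBS 0.8 h replicate 1 (adjusted p = 0.168) and without PBS 12 h replicate 1 (adjusted p = 0.0862). At 3 h 2 of its members rose and 2 fell, or 0 to 4 and 1 to 3 with single arrays left out, and 0 rose without PBS 3 h replicate 4, NmU 3 h replicate 2 or NmU 3 h replicate 3. At 6 h 1 rose and 2 fell, and 0 rose without any 1 of the 8 arrays of that time. Glycolysis shifted upward at 0.8 h with 0 of 15 members called, or 1 adjusted over the list alone (adjusted p = 0.00359, and adjusted p = 0.120 with an estimated correlation). At 3 h 1 of its members rose and 1 fell and at 6 h 1 rose, calls that were lost in several fits with 1 array left out.

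Programmes of cell death and protein folding did not shift at any time, and most single calls in this paragraph were lost without 1 or more of the arrays. Of 12 apoptosis genes 1 rose at 0.8 h, 1 rose and 2 fell at 3 h, and 3 rose at 6 h, or 1 higher, 2 higher and 2 lower, and 3 higher adjusted over the list alone. At 6 h 1 rose without NmU 6 h replicate 4, and 0 without PBS 6 h replicate 1 or 2 or NmU 6 h replicate 1 (camera adjusted p = 0.0894, 0.798, 0.232 and 0.610 in order of time). Of 10 heat shock genes 1 fell at 3 h, also adjusted over the list alone, where 1 was lower at 12 h too (adjusted p = 0.871, 0.906, 0.112 and 0.588). Of 14 genes of the unfolded protein response 1 rose and 1 fell at 6 h and 1 fell at 12 h, also adjusted over the list alone (adjusted p = 0.610, 0.928, 0.427 and 0.610). Of 5 Th1 identity genes 1 rose at 0.8 h and 1 rose and 1 fell at 3 h, or 1 higher and 1 lower at both times adjusted over the list alone (adjusted p = 0.572, 0.644, 0.700 and 0.828).

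Of 12 measured genes of the neuromedin receptors and of Gq signalling, the pathway through which NmU acts, 0 were called at any time, also adjusted over the list alone (camera adjusted p = 0.908, 0.328, 0.908 and 0.207). Nmur1 itself differed by -0.06 ± 0.25 at 0.8 h, -0.67 ± 0.27 at 3 h, 0.39 ± 0.25 at 6 h and -0.57 ± 0.25 at 12 h (SE, limma adjusted p = 0.993, 0.112, 0.449 and 0.380). Without PBS 3 h replicate 4, Nmur1 was lower at 3 h by 1.06 on the log2 scale (adjusted p = 5.09e-04). With array weights and all arrays kept it was lower by 0.87 (adjusted p = 0.00469).

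Markers of cell types other than T cells were seldom called. Of 8 T cell markers, Zap70 rose at 3 and 6 h, the call at 6 h being lost without NmU 6 h replicate 2, with 1 and 2 higher adjusted over the list alone (camera adjusted p = 0.429, 0.429, 0.801 and 0.112 in order of time). Of 8 markers of B cells and antigen presenting cells 0 were called, or 1 higher at 12 h adjusted over the list alone (adjusted p = 0.993, 0.928, 0.754 and 0.260). Of 7 markers of macrophages and dendritic cells 1 rose at 6 h and 1 at 12 h, calls lost in several fits with 1 array left out, or 1 and 2 adjusted over the list alone, where 1 was lower at 3 h (adjusted p = 0.610, 0.798, 0.233 and 0.427). Lists with too few measured genes for camera were cytotoxic and NK cell markers (0 of 1 called), erythroid markers (0 of 2) and mast cell and granulocyte markers. Of 4 of the latter, the peroxidase Mpo rose at 6 h, by 0.86 ± 0.18 from a dim signal of 18.5 ± 3.41 (SD, n = 4), while the mean over all its probe sets was not called (0.34, adjusted p = 0.228).

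A core of 8 named genes was called at all 4 times, always higher, namely Il4, Il6, Il10, Il13, Ccl4, Gem, Lilr4b and Gch1, the last chosen after its values were seen. Among these, the Ccl4 call at 12 h was lost in several fits with 1 array left out. With only the 2 groups compared, Ccl4 and Il6 were not called at 12 h (limma adjusted p = 0.110 and 0.0732). Over all probe sets, the effect of NmU differed between times for 320 probe sets (275 named genes, limma F test), and for 210 without NmU 3 h replicate 3. Fold changes of all probe sets correlated at 0.444 between 3 and 6 h, 0.281 between 6 and 12 h and 0.148 between 0.8 and 3 h, a description since genes are not independent. At 3 and 6 h 77 probe sets were lower at both times, against 9.22 expected from the counts, 117 were higher at both, and 1 was called in opposite directions.

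Few transcripts were called for time alone in PBS-treated cells. Ddit4 was the 1 probe set called by the F test over time in PBS, rising between 0.8 and 12 h by a log2 fold change of 0.79 (limma adjusted p = 0.00941). The F test called 3 without PBS 3 h replicate 2, and 2 without PBS 3 h replicate 4 or without NmU 6 h replicate 4. Between 0.8 and 3 h limma called 0 probe sets in PBS, with 656 at an unadjusted p under 0.05.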

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

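In this part, the 3 tests of NmU 6 h replicate 4 were chosen after its values were seen.

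Single arrays that lay far from the rest of their group were looked for with Dixon's test in each group of 4 arrays. It marked 14 of 204 groups of gene signals and 3 of 35 groups of array measures, where chance marks about 1 in 20 groups. At 0.8 h in PBS, replicate 1 held low Il13 (1078.8, others 1529.6 to 1629) and Ccl7 (37.4, others 76.3 to 85.3). PBS 3 h replicate 4 held low Ccl7 (13.8, others 69.7 to 81.3) and Nmur1 (88.1, others 247 to 266). At 6 h in PBS, replicate 1 held high Il5 (63.5, others 46.9 to 49.0), replicate 3 held low Il10 (1429.9, others 1651.3 to 1682.7) and low Dusp6 (1294.8, others 1653.1 to 1723.7), and replicate 2 held low Fosl1 (21.4, others 41.3 to 43.4). At 12 h, low values stood out for Traf1 in PBS replicate 2 (10.7, others 18.8 to 20.4), Lag3 in PBS replicate 4 (742.9, others 818 to 828.5), Nmur1 in PBS replicate 4 (153.3, others 205 to 212) and Ccl4 in NmU replicate 4 (29.5, others 41.3 to 42.6). NmU 6 h replicate 4 held high Egr2 (1705.4, others 252 to 304) and high Dennd5a (834.1, others 597 to 631.5). Among array measures, the ratio of 3' to 5' actin signal was low in NmU 6 h replicate 2 (0.963, others 1.09 to 1.11), and the 18S ribosomal RNA signal was high in NmU 0.8 h replicate 3 (1610.4, others 74.6 to 110.2) and PBS 3 h replicate 4 (2269.2, others 115.3 to 249).

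NmU 6 h replicate 4 carried immediate early transcripts at levels between those of the 6 h and 0.8 h groups. Its Egr1 signal was 1586.7, against 156 as the mean of the other 6 h arrays and 3499.9 at 0.8 h. On a scale from 0 at the other 6 h arrays to 1 at 0.8 h, 24 probe sets that were lower at 0.8 h had a median position of 0.519 on this array. All 24 were moved towards the 0.8 h level. Each other 6 h array was scored on its own probe sets against a mean that held replicate 4, which pulls its position below 0. The highest median of these was -0.0990, which is therefore no independent baseline. The 24 included Klf10 and Gadd45b, which NmU itself lowered at 0.8 h, so that a second stimulus could move these too. With quartiles of 0.460 and 0.565 around it, the median position of 0.519 argues against a second stimulus before harvest with no other change. Without an independent baseline it does not exclude one. Late transcripts lay at a median position of 0.432 between the higher of their 0.8 and 3 h levels (0) and the other 6 h arrays (1), which excludes a single mislabelled culture of a time between 0.8 and 3 h. RNA of cells at 0.8 h in this sample remains a candidate explanation, and other mislabelled cultures or cells stimulated at different times were not tested. The array also had a low signal of the hybridisation control BioC, 97.1 against 196, 202.5 and 218.3 on NmU 6 h replicates 1, 2 and 3, which Dixon's test did not mark.

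The effect of NmU differed between times for 55 of the 77 genes named with values in the text, by the moderated F test on differences between times. Many of these genes were picked from the same data for a large change or a low p at a single time, which favours such differences. Over all probe sets, 320 of 7930 differed, so that the share among the 77 holds for this choice of genes only. The F test does not show which time has the largest effect, and several genes had near-equal effects at different times. Il10, for example, rose by 1.36 at 0.8 h and by 1.34 at 3 h. Adjusted p-values of the F test follow, grouped by the time of the largest point estimate. At 0.8 h they were Gadd45b 2.91e-05, Zfp36 2.91e-05, Ier2 4.80e-05, Egr2 5.13e-05, Egr1 1.38e-04, Fos 6.18e-04, Ccr8 0.00131, Tiparp 0.00226, Junb 0.00239, Irf1 0.00297, Dusp1 0.00566, Gfi1 0.00603, Klf10 0.00683, Tnf 0.00751, Nr4a1 0.00937, Ctla4 0.0109, Il10 0.0215 and Il6 0.0308. For genes with the largest effect at 3 h they were Ccl2 2.91e-05, Crem 2.91e-05, Il4 2.91e-05, Myb 2.91e-05, Tnfsf8 6.00e-05, Apaf1 9.20e-05, Ccl1 1.44e-04, Ccl7 2.80e-04, Adgrg1 7.58e-04, Cxcr4 0.00284, Slfn2 0.00362, Cd44 0.00613, Nfia 0.00621, Irf4 0.00969, Lyst 0.0124, Relb 0.0150, Aurka 0.0158, Ccnd2 0.0190, Zap70 0.0339, Il13 0.0393, Lilr4b 0.0412, Mef2c 0.0421 and Dusp6 0.0443. With the largest effect at 6 h they were Msmo1 0.00376, Ddit4 0.00393, Dennd5a 0.00401, Cxcl2 0.0201, Sqle 0.0256, Gem 0.0293 and Idi1 0.0314. With the largest effect at 12 h they were Pth 2.91e-05, Il5 4.32e-05, S100a13 7.99e-05, Il1r2 0.00603, S100a1 0.0212, Fabp5 0.0357 and Traf1 0.0388. Gadd45b moved from -0.69 at 0.8 h to 0.66 at 3 h.

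Array controls for Il4 and Il10, which the comparisons above leave out, also carried signal above that of PBS arrays. With NmU the Il4 control averaged 1507.2, 2704.6, 1756.8 and 971.85 at 0.8, 3, 6 and 12 h, against 308, 295, 353 and 331 in PBS. For the Il10 control these were 3223.1, 2516.1, 2127.4 and 1718.2 with NmU, against 1129.6, 957, 1105.3 and 1094.8 in PBS. Every NmU array lay above every PBS array of its time (exact p = 0.0286 each, the smallest possible, adjusted p = 0.129 over all array measures).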

How the results depend on the processing

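Leaving out NmU 6 h replicate 4 and PBS 3 h replicate 4 together was chosen after seeing the data; the other alternatives were chosen before the data were examined. No tested gene or list changed direction and passed in both. The direction that held more calls turned with arrays scaled to a common median, to 448 higher and 337 lower at 3 h and 175 and 204 at 6 h, and with quantile normalisation at 3 h, to 415 and 411. Where a value moved the cause was not tested.

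With array weights, 109 probe sets were called at 0.8 h, 677 at 6 h, 552 for effects that differed between times and 4 for time in PBS. At an adjusted p under 0.01 the counts were 447 at 3 h, 172 at 6 h, 53 at 12 h, 525 at any time and 122 for differences between times. With only the 2 groups compared, 171, 164 and 56 probe sets were called at 3, 6 and 12 h, so that the counts at 3 and 6 h were near each other. Named genes not called in this way also included Il3, Ctla4, Cd44, Zap70, Irf4 and Gadd45b at 3 h, Egr2 and Cxcr4 at 6 h, Il6 and Ccl4 at 12 h and Gfi1 at 0.8 h. With at least 1.5-fold required they were 460, 192 and 65. The floor at the 40th percentile gave 2 probe sets for time in PBS and a correlation of effects between 3 and 6 h of 0.513, no filter gave 0.327 and a filter at the 60th percentile 0.618. With an estimated correlation 19 list shifts were called. Whether replicate numbers pair arrays stayed undecided: 5 of 15 same-number pairs had residuals correlated above 0.1 (range -0.224 to 0.204, median 0.0567, other pairs -0.0129), and 7 of 15 NmU arrays matched their own number best. With the number as a block within times, 67, 826, 438 and 91 probe sets were called at the 4 times and 0 for time in PBS, and Nmur1 was lower at 3 h by 1.06 (adjusted p = 8.41e-04). Il3 was called at 0.8 and 12 h with this block (adjusted p = 0.00310 and 5.99e-04). With a block across times the counts were 67, 754, 372 and 86. Leaving out both arrays that stood apart gave 4 for time in PBS and a correlation of 0.392. With each array left out in turn, counts ranged from 55 to 81 at 0.8 h, 560 to 918 at 3 h, 238 to 500 at 6 h, 66 to 125 at 12 h, 713 to 1043 at any time, 210 to 390 for differences between times and 1 to 3 for time in PBS. The correlation ranged from 0.402 to 0.446, and list shifts from 37 to 41.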

Other observations

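In this part, the tests that leave out PBS 3 h replicate 4 and that rescale the arrays were chosen after results were seen.

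Ddit4, an inhibitor of the growth kinase mTOR, rose in PBS from 287 ± 18.1 at 0.8 h to 611 ± 24.1 at 6 h (SD, n = 4 each), while NmU-treated cells held 180 ± 11.3 and 284 ± 20.4 (SD, n = 4 each). At 12 h both treatments were near each other, at 499 ± 67.0 and 473 ± 83.1 (SD, n = 4 each). Several dim transcripts were lower at 3 h with NmU. The phosphatase Lpin1 fell by 2.01 on the log2 scale (SE 0.33), the lysosomal trafficking gene Lyst fell by 2.16 (SE 0.45) and the transcription factor Nfia fell by 1.71 (SE 0.26), the last 2 with 1 of 3 NmU arrays at the floor. Nfia was not called with the floor at the 40th percentile (-0.25, adjusted p = 0.228), nor Lyst with only the 2 groups compared (adjusted p = 0.0937).

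Counts of calls were set beside those from other groupings of the same arrays. At 0.8 h 67 probe sets were called and the highest other of 35 splits gave 2, at 6 h 387 against 1, and at 12 h 100 against 32, and in each case 1 of 35, the real split, was as large. At 3 h 806 were called against 629 in the split that puts PBS 3 h replicate 4 with the NmU arrays, again with 1 of 35 as large. Chance assignment of the arrays is excluded for these counts, for 922 probe sets at any time (1 of 100 draws, highest other 222) and for 320 that differed between times (1 of 100, highest other 15). Such regroupings take arrays as independent, so differences between cultures are not covered if replicates were technical. Chance is not excluded for the 1 probe set changed with time in PBS (11 of 100 draws, highest other 7). The number of shifted lists was 10 at 0.8 h (3 of 35 splits as large, highest other 13), 10 at 3 h (6 of 35, highest other 11), 9 at 6 h (3 of 35, highest other 9) and 10 at 12 h (1 of 35, highest other 8). Chance is therefore not excluded for this number at 0.8, 3 and 6 h. At 12 h no other split gave as many, without adjustment over the 4 times.

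List by list, the camera p of the real split was set beside those of the other splits. The real split alone gave the smallest p for 7 of the 10 lists called at 0.8 h and 4 of 10 at 3 h. It did so for 6 of 9 at 6 h and 5 of 10 at 12 h. As 1 of 35 is the smallest share possible and was not adjusted over lists, it does not exclude chance for a single list. Th2 cytokines and chemokines were among the lists with the smallest p in the real split at all 4 times. For Th2 cytokines the p was 8.86e-22, 2.89e-16, 3.45e-17 and 9.93e-23 in order of time, against 5.14e-08, 8.22e-12, 1.83e-09 and 1.54e-09 as the smallest of the other splits. Calcineurin and NFAT targets were among them at 0.8, 3 and 6 h, immediate early genes at 0.8, 3 and 12 h, and cholesterol synthesis at 6 and 12 h (1.81e-14 against 4.11e-11 at 6 h). At 12 h the margins were narrow, with a camera p of 0.0181 against 0.0291 for immediate early genes and 7.23e-05 against 7.72e-05 for cholesterol synthesis. For the other called lists, other splits gave a p as small. At 0.8 h these were NF-kB targets, glycolysis and interferon-induced genes, with 3, 3 and 6 of 35 splits as small (0.00512, 0.00117 and 4.46e-04, against 0.00234, 1.49e-04 and 4.76e-05 as the smallest others). At 3 h they were mitosis, DNA replication, activation markers and ribosome biogenesis, with 7, 14, 9 and 9 of 35 (5.01e-07, 3.60e-04, 5.43e-04 and 1.37e-04, against 1.48e-11, 3.83e-12, 1.06e-06 and 2.23e-09), and NF-kB targets and feedback regulators, with 2 of 35 each (7.05e-04 and 0.00939, against 1.99e-04 and 0.00359). At 6 h they were mitosis, immediate early genes and ribosome biogenesis, with 3, 5 and 5 of 35 (8.78e-08, 1.60e-07 and 0.00858, against 7.07e-09, 9.80e-09 and 2.52e-04). At 12 h they were DNA replication, calcineurin and NFAT targets, NF-kB targets, ribosome biogenesis and interferon-induced genes, with 2, 3, 3, 3 and 5 of 35 (1.70e-04, 0.00354, 0.00717, 0.0110 and 0.00781, against 9.88e-05, 0.00266, 0.00234, 0.00410 and 0.00251).

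The 41 genes of mitosis and DNA replication were lower with NmU by 0.18 on the log2 scale as a mean over the 4 times, and by 0.03, 0.30, 0.21 and 0.19 at 0.8, 3, 6 and 12 h (exact p = 0.657, 0.0571, 0.0286 and 0.0286, adjusted over times 0.657, 0.0762, 0.0571 and 0.0571). At 6 and 12 h the exact p was the smallest these arrays can give, 0.0286. With PBS 3 h replicate 4 and NmU 6 h replicate 4 left out, the difference was -0.202 at 3 h and -0.250 at 6 h. Which time held the largest shift therefore depended on these arrays. For the mean over times, a permutation of treatment labels within times gave p = 4e-05, which excludes chance assignment of the arrays. The permutation takes arrays as independent. If replicates of a group were technical, it cannot tell chance differences in cycling between cultures from an effect of NmU. With the 18S signal as a covariate the shift kept a ratio of 1.02 of its size, which excludes this signal as the sole cause. With arrays scaled to their medians it kept 0.892, which excludes the choice of means over medians for the scaling as the sole cause. Both scalings are relative to the other transcripts on the array. A change of total signal with NmU could not be seen with either scaling and is not excluded. Slower cycling of NmU-treated cells is a possible explanation that was not tested.

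Most calls fell at 3 h. Without PBS 3 h replicate 4, 918 probe sets were called at 3 h and 500 at 6 h, and with the 18S covariate 924 and 451, which excludes both as the cause of the higher count in this model. With only the 2 groups compared the counts were 171 and 164, near each other. That comparison kept PBS 3 h replicate 4 and was not run without it, so why its counts lay closer cannot be told. A stronger response of the cells at 3 h may or may not explain the higher count in the fit of all arrays and was not tested.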
